A study of Drosophila melanogaster with 8 samples.

How the data were processed

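Poly(A) RNA of whole flies was made into stranded libraries and sequenced as paired ends, per the labels' protocols. The 8 samples fall into 5 controls and 3 DHR39 mutants by the genotype label, and replicate numbers follow accession order and only name a library. Per the submitters' processing notes, cutadapt 1.16, STAR 2.6.1b, featureCounts 1.6.3 and DESeq2 1.20.0 and 1.22.2 were used, with the builds BDGP6 and dm6 named. The deposited table of raw counts per gene was the starting point: it holds 14865 genes, 5 of them at 0 in all libraries. The deposited sample sheet gives a size factor per library, the ratio by which the authors scaled counts, and replicate names. Deposited tables of scaled counts and regularized log values were not used here.

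Whether reads were counted by strand is not given in the sources used here, so values of overlapping genes are uncertain. Of the genes named in the results, CG31883, CG42564, CR43787, CR44050, CR45994, Hr39 and Sfp87B overlap another gene on the same strand, and Abd-B, AttC, CG31626, Cyp6a9, Est-6, Hr38, Hsp83, SPH93, Sfp65A, Tps1, UQCR-C2, apolpp, dsf, frma, hdly, lectin-24A, per and sad on the opposite strand.

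The authors' deposited comparison tables give log2 fold changes, p-values and adjusted p-values from DESeq2, and a mean scaled signal per gene. That signal differs by over 10 percent from the mean of these 8 libraries for 2452 genes, so that table does not rest on these 8 libraries alone. The deposited table named for the DHR39 line holds another comparison by its values: its calls match 506 of 506 entries that the authors' deposited set column gives for another line, E7818.37. The authors' deposited table for DHR39 calls 2825 genes, of which 2282 were among the 2333 called here, all in the same direction. Both rest at least in part on the same libraries, so this overlap is no independent check.

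Genes were filtered with filterByExpr at its defaults, which left 13506 of 14865. Factors were set by TMM, and DHR39 was tested against control with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Calls are at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and the biological coefficient of variation was 14.9%. The SE of a log2 fold change is its size divided by the square root of the F statistic. Positions came from Ensembl annotation release 115 of the BDGP6 assembly, matched by gene identifier for 13412 of the tested genes (99.3%). Where a group had no counts, a bound was set against 3 counts over the group, and with 1 to 3 counts a ratio is given with an exact 95% binomial interval. In single libraries, 3 counts correspond to between 0.150 and 0.187 CPM.

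Before the data were examined, 33 gene lists were fixed, and 31 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. A list of mitochondrially encoded genes had no member in the table. A correlation estimated from the libraries and fry were set beside it, and fry called 13 lists, 9 of them also called by camera. Genes named were Hr39, its flanking genes, the 12 largest rises and 12 largest falls among called genes with an average log2 CPM of at least 0 and no overlap of CPM between the groups, and up to 4 called members per list with the smallest p. Up to 2 uncalled members of highest CPM could be named per list, which was done for 6 lists, always both. Also fixed beforehand were the alternatives: other scalings and filters, DESeq2 1.42.0, limma voom, a robust fit, a surrogate variable from sva 3.50.0, leaving out each library, and leaving out arm 2L.

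Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom from 17.7 to 44.8, so no library was taken for a repeat of another. Replicate names in the deposited sample sheet join each DHR39 library to 1 control. Deviations from the group means correlated across genes at 0.215, 0.108 and 0.183 within these pairs, each above 0.1, so the names were taken to pair samples. The margin was narrow: of the other combinations, DHR39 replicate 1 with control replicate 2 was also above 0.1, at 0.101, and the next reached 0.0927. Each DHR39 library correlated most with the control of its own name. Genes are not independent replicates in these correlations. A fit with the names as a block was added after seeing the data, and its value stands beside a result where it changes the call. Control replicates 1 and 2 have names that no DHR39 library shares, so in that fit they add nothing to the contrast. The block values therefore rest on the 3 pairs, with fewer residual degrees of freedom than the main fit. All 56 divisions of the libraries into 5 and 3 were refitted. These, like the exact permutation tests, leave the pairs out of account, and 8 of the 56 part all 3 pairs as the genotypes do.

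The procedure was tested on simulated data with the gene means of the controls and the spread of all 8 libraries. In 10 draws with 200 changed genes among 13260 to 13282 tested for the DHR39 comparison, 44.4% of 1.5-fold, 83.0% of 2-fold and 97.4% of 4-fold changes were recovered, and 5.85% of calls were false. Genes were drawn independently and fewer changed than the 2333 called in the data, so these shares need not hold there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.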

Results

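Messenger RNA of whole adult Drosophila melanogaster was sequenced from mutants of DHR39 (gene symbol Hr39), a nuclear receptor, and from controls. All flies were at day 8 of adulthood on a diet of 8% yeast and 9% sugar. The table held 5 control and 3 DHR39 libraries, and the controls were re-used from another series. The labels do not state the sex of the flies, and the series title places the question in male fertility and accessory gland expression. Total counts per library ran from 16072497 to 19935574 and did not differ between the groups by more than the spread (two-sided exact permutation p = 0.518). Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Below, CPM are means ± SD (n = 5 controls, n = 3 DHR39), and log2 fold changes are DHR39 minus control ± SE.

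The targeted transcript was measured first. Hr39 (FBgn0261239), a protein-coding gene at 2L from 21237250 to 21259675 on the BDGP6 assembly, was still expressed in the mutant, at 27.0 ± 2.89 CPM against 36.2 ± 2.38 CPM in controls. The labels do not describe the lesion of the allele, so this level is a weak check of the genotype label. In the DHR39 libraries Hr39 was at 24.4, 26.5 and 30.1 CPM, and in the controls at 39.9, 34.6, 33.8, 35.6 and 37.0 CPM. Hr39 fell by 0.42 ± 0.10 on the log2 scale (edgeR quasi-likelihood adjusted p = 0.0119). That call ended without DHR39 replicate 1 (edgeR adjusted p = 0.0515), without DHR39 replicate 2 (0.0508) and with library totals alone as the scale (0.0593), in a range of 0.00250 to 0.0593 over the alternatives. The authors' deposited table for DHR39 gives Hr39 a log2 fold change of -0.41. Another annotated gene overlaps Hr39 on the same strand, so its reads are uncertain to that extent. The flanking genes did not pass the test, CG31626 at a log2 fold change of -0.54 ± 0.35 (edgeR adjusted p = 0.362, with a change of -0.86 without DHR39 replicate 1 and -0.24 without DHR39 replicate 2) and l(2)k14505 at 0.15 ± 0.11 (0.406).

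**Figure D1:**
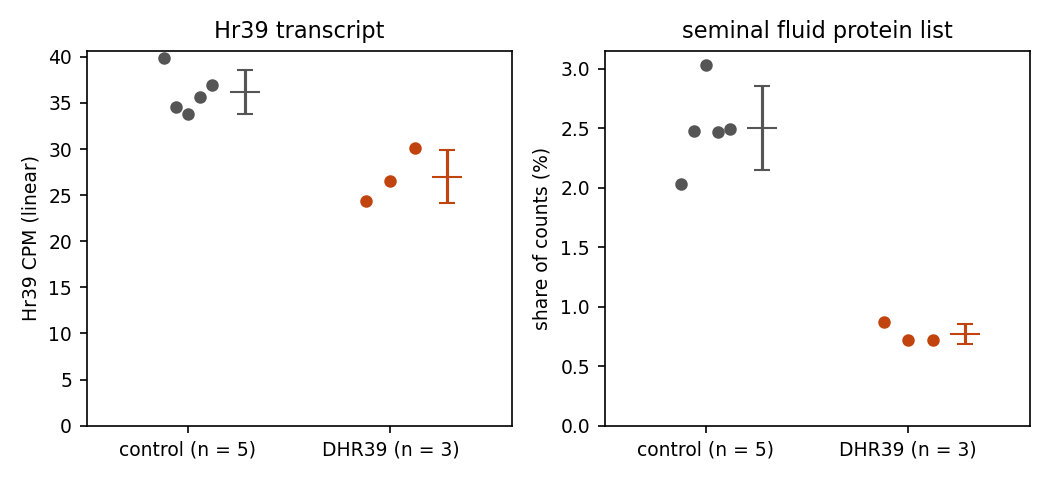
Left, CPM of Hr39 in each library; right, percent of each library's counts taken by the seminal fluid protein list. Points are libraries and bars the mean and SD, and in both panels the 3 DHR39 libraries lie below the 5 controls.

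In DHR39 flies RNA fell for 83 of 95 seminal fluid proteins and 8 of 13 products of the ejaculatory duct and bulb, and rose for 30 of 40 antimicrobial and other immune induced genes. Of 55 digestive enzymes 34 fell, 4 rose and 17 did not pass. The calls of the antimicrobial and digestive lists ended with an estimated correlation (camera adjusted p = 0.0560 and 0.262), while fry called both (fry adjusted p = 0.00122 and 0.00440). Seminal fluid genes took 0.770% ± 0.0868 of all counts in DHR39 (SD, n = 3) and 2.50% ± 0.355 in controls (SD, n = 5), with a two-sided exact permutation p of 0.0179, the smallest that 8 libraries divided this way can give. Most genes of spermatogenesis did not pass the test. In all, 2333 of 13506 tested genes changed (edgeR quasi-likelihood, adjusted p under 0.05), 889 higher and 1444 lower in DHR39, and 929 of them changed at least 2-fold, 249 higher and 680 lower. The division into higher and lower depends on the scale. It was 1997 higher and 1040 lower with library totals alone, which put the median log2 fold change of all genes at 0.14, and 1479 higher and 1132 lower with totals that leave out the 50 most abundant genes. Without DHR39 replicate 3, 1566 genes were called. By arm, 619 of 2628 tested genes were called on 2L, which holds Hr39, 564 of 2717 on 2R, 365 of 2614 on 3L, 517 of 3363 on 3R and 248 of 2063 on X. The share was 23.6% on 2L and 15.8% elsewhere (Fisher's exact p = 3.4e-20, across genes, which are not independent).

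Seminal fluid proteins are made mostly in the male accessory gland and passed to the female at mating. Of 95 tested members of that list, 83 fell, 1 rose and 11 did not pass the test, and adjusted over the list alone 89 fell and 2 rose. With library totals alone 2 rose. The median log2 fold change was -1.67 (camera adjusted p = 5.1e-95, and adjusted p = 0.0454 with an estimated correlation). CG17097 fell by 2.92 ± 0.10, from 4075 ± 270 to 538 ± 21.1 CPM (edgeR adjusted p = 6.5e-09). CG14034, Acp98AB and CG42564 also fell, with log2 fold changes of -2.62 ± 0.13, -2.74 ± 0.17 and -2.24 ± 0.11. Not passing were Sfp87B, at a log2 fold change of -0.78 ± 0.31 (edgeR adjusted p = 0.115, and 0.00744 with replicates paired as a block), and Sfp60F, at -1.16 ± 0.48 (0.130). Control replicate 2 stood far above the other controls for Sfp60F, and without it these log2 fold changes were -0.40 and -0.49, against -0.49 and -0.57 with the block.

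The sex peptide network is a set of male and female proteins that act with the seminal sex peptide in mated females. Of its 14 tested members 10 fell and 4 did not pass, and adjusted over the list alone 10 fell and 1 rose. With library totals alone 1 rose over all genes. The median log2 fold change was -1.21 (camera adjusted p = 1.8e-12, and adjusted p = 0.0560 with an estimated correlation). SP, the sex peptide itself, fell by 2.31 ± 0.18, from 146 ± 25.2 to 29.5 ± 6.57 CPM (edgeR adjusted p = 4.1e-06). CG17575 and antr fell too, at log2 fold changes of -1.26 ± 0.10 and -1.54 ± 0.13. This list shares 9 tested members with the seminal fluid list, so the counts are not independent. Not passing were hdly, at 0.30 ± 0.11 (edgeR adjusted p = 0.0768, 0.0141 with the block and 0.0131 without control replicate 2), and frma, at 0.11 ± 0.14 (0.686).

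Products of the ejaculatory duct and bulb, male organs downstream of the gland, fell in 8 of 13 tested genes and did not pass in 5, and adjusted over the list alone 11 fell. The median log2 fold change was -1.03 (camera adjusted p = 6.1e-12, and adjusted p = 0.0445 with an estimated correlation). Est-6, a carboxylesterase of the duct, fell by 1.23 ± 0.10, from 1505 ± 121 to 642 ± 57.2 CPM (edgeR adjusted p = 5.9e-06). Sfp65A and Obp22a fell as well, at log2 fold changes of -2.50 ± 0.17 and -2.14 ± 0.15. This list shares 4 tested members with the seminal fluid list and 3 with odorant binding proteins, so it is not independent of them. Not passing were the bulb proteins Ebp, at -0.80 ± 0.33 (edgeR adjusted p = 0.128), and EbpII, at -1.03 ± 0.37 (0.0809, 0.00173 with the block and 0.0407 without control replicate 1). Without control replicate 2 these were -0.38 and -0.60, and Ebp was -0.32 with the block. Of 10 genes of secondary cell identity, a minor secretory cell type of the gland, 1 fell and 0 rose, over all genes and adjusted over the list alone, against 1 and 4 with library totals alone (camera adjusted p = 0.946). The gene that fell was Abd-B, a Hox gene, at -0.48 ± 0.091 (edgeR adjusted p = 0.00318).

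**Figure D2:**
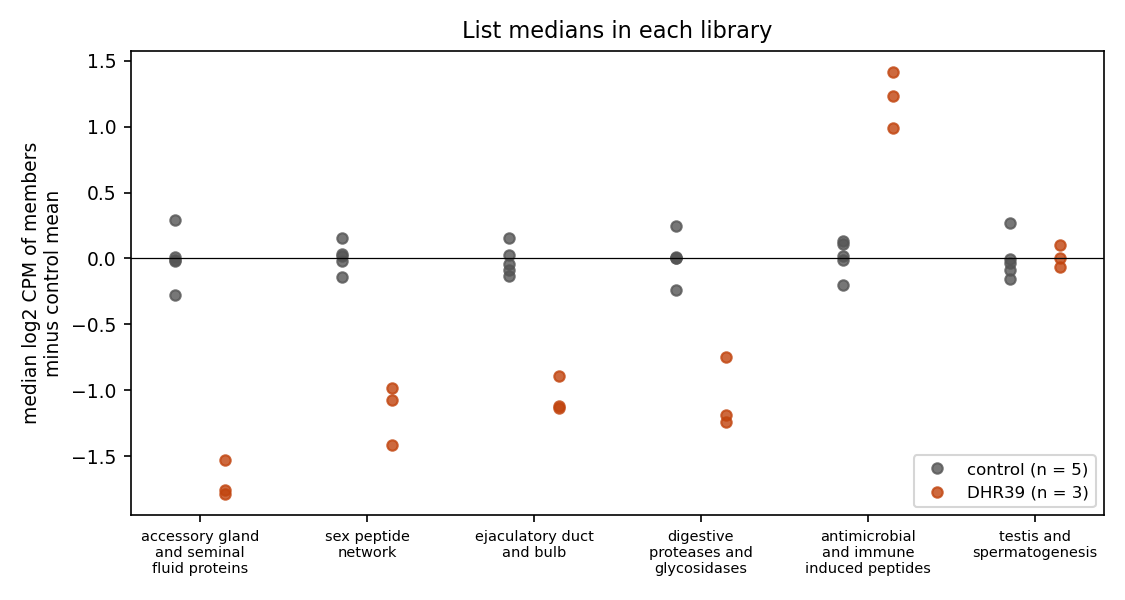
Median over the members of each of 6 gene lists of log2 CPM minus the control mean, for each library (grey, 5 controls; orange, 3 DHR39). For the antimicrobial list, DHR39 libraries lie at 0.99, 1.23 and 1.42 and controls between -0.20 and 0.13.

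Few genes of the germline lists passed the test. Of 71 tested genes of testis and spermatogenesis, 1 rose, 2 fell and 68 did not pass, as also when adjusted over the list alone (median log2 fold change -0.0012, 0.14 with library totals alone, as for all genes; camera adjusted p = 0.672). Mst36Fb was close to absent in DHR39, at 72.3 ± 9.28 CPM in controls and 0.108 ± 0.116 CPM in DHR39 (edgeR adjusted p = 6.5e-09). CG31883, which overlaps another gene on its strand, fell by 3.26 ± 0.18, and Mst84Db rose by 0.52 ± 0.12. Mst36Fb and CG31883 lie on arm 2L, which holds Hr39, and an effect of linked sequence on these single genes was not tested. The abundant members S-Lap1, at -0.016 ± 0.10 (edgeR adjusted p = 0.946), and loopin-1, at 0.073 ± 0.10 (0.723), did not pass. Of 13 Y-linked genes 1 rose, over all genes and adjusted over the list alone, against 3 with library totals alone (median 0.24, also with that gene at its bound; camera adjusted p = 0.0277, and adjusted p = 0.469 with an estimated correlation). The list's call ended with the block (0.105) and with DESeq2 (0.0553), in a range of 0.0142 to 0.105. The gene was Pp1-Y1, with no counts in the 5 controls and 2.68 ± 0.839 CPM in DHR39, at least 78.7-fold higher against a floor of 3 counts over the group.

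Antimicrobial peptides and other genes induced by infection rose in 30 of 40 tested members, 1 fell and 9 did not pass, and adjusted over the list alone 34 rose and 1 fell. The median log2 fold change was 1.29 (camera adjusted p = 6.4e-27, and adjusted p = 0.0560 with an estimated correlation). DptA, a diptericin, rose by 4.66 ± 0.36, from 3.97 ± 1.68 to 101 ± 47.1 CPM (edgeR adjusted p = 4.1e-06). The attacins AttC and AttA rose by 3.49 ± 0.27 and 3.28 ± 0.29, and Dro, a drosocin, rose by 4.49 ± 0.45 (3.63 without DHR39 replicate 3) and spread widely in DHR39, at 107 ± 83.3 CPM. Not passing were Tsf1, a transferrin, at 0.59 ± 0.24 (edgeR adjusted p = 0.126, 0.000119 with the block and 0.0194 without control replicate 1), and IM2, at 0.61 ± 0.20 (0.0623, 0.000627 with the block and 0.00777 without DHR39 replicate 2). Of 24 genes of haemocytes and melanisation 6 rose and 1 fell, over all genes and adjusted over the list alone, against 10 and 1 with library totals alone (median 0.13; camera adjusted p = 0.0188, and adjusted p = 0.765 with an estimated correlation). That list's call ended without DHR39 replicate 1 (0.0559, in a range of 0.00533 to 0.0559). The serine protease gene grass rose by 1.17 ± 0.10, PPO3 by 2.61 ± 0.36 and the scavenger receptor gene Sr-CI by 1.27 ± 0.19, and ItgaPS5 fell by 4.26 ± 0.86.

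No gene of 21 heat shock genes was called by edgeR, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05, while DESeq2 and voom called 0 and the block 4 higher (camera adjusted p = 0.599). Hsc70-4 stood at a log2 fold change of 0.12 ± 0.12 (edgeR adjusted p = 0.597) and Hsp83 at 0.48 ± 0.35 (0.428, and 0.00664 with the block). Hsp83 was at 0.040 without DHR39 replicate 3, 0.32 without control replicate 3, 0.73 without control replicate 5 and 0.78 without DHR39 replicate 1. Relative to the control mean, the list's median on the log2 scale stood apart in control replicate 5, at 1.33, and DHR39 replicate 3, at 1.74, which share a replicate name, against -0.73 to 0.16 in the other libraries. It was higher in the DHR39 library of each of the 3 pairs, the others being control replicate 3 and DHR39 replicate 1, at -0.62 and -0.34, and control replicate 4 and DHR39 replicate 2, at -0.36 and 0.091.

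Digestive proteases and glycosidases fell in 34 of 55 tested members, 4 rose and 17 did not pass, and adjusted over the list alone 39 fell and 4 rose. The median log2 fold change was -1.07, also with epsilonTry at its bound (camera adjusted p = 3.8e-12, and adjusted p = 0.262 with an estimated correlation). The mannosidase genes LManIV and LManIII fell, from 14.1 ± 1.64 to 1.44 ± 0.222 CPM and from 72.2 ± 9.32 to 11.9 ± 2.59 CPM (edgeR adjusted p = 2.7e-07 and 8.6e-07). The same list held the largest rises among the genes named by rule. The trypsin gene epsilonTry had no counts in controls and 44.5 ± 4.13 CPM in DHR39, at least 1298-fold higher against 3 counts over the group, and its neighbour betaTry rose from 0.382 ± 0.199 to 902 ± 184 CPM (edgeR adjusted p = 2.8e-10). Trypsin genes of this cluster resemble each other, so reads may be split between copies and their separate values are uncertain.

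Detoxification enzymes moved both ways. Of 79 cytochrome P450s 12 rose and 22 fell, against 19 and 18 with library totals alone, and adjusted over the list alone 15 rose and 23 fell (camera adjusted p = 0.761). Within 1 cluster on 2R, Cyp6a17 rose from 0.503 ± 0.248 to 97.1 ± 23.2 CPM and Cyp6a8 rose by 4.54 ± 0.35, while Cyp6a20 fell by 2.34 ± 0.10 and Cyp6a9 fell by 1.38 ± 0.10. Of 35 glutathione transferases 9 rose and 3 fell, and adjusted over the list alone 9 rose and 4 fell. Their mean log2 fold change was 0.28 and camera pointed up (adjusted p = 0.0373, and adjusted p = 0.776 with an estimated correlation), whereas the median was -0.027, turning to 0.12 with library totals alone. The camera call ended without control replicate 3 (0.0875), without control replicate 4 (0.109) and without DHR39 replicate 1 (0.0641), among others, in a range of 0.00194 to 0.218. GstD2 rose by 3.46 ± 0.35, GstD10 by 1.84 ± 0.16 and GstD1 by 1.11 ± 0.12, the last from 537 ± 75.2 to 1161 ± 96.3 CPM. Members of both families share sequence, so single values are uncertain.

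Some genes of energy metabolism fell, and their number depended on the scale. Of 82 nuclear genes of oxidative phosphorylation 22 fell, against 1 lower and 1 higher with library totals alone, and adjusted over the list alone 35 fell (median -0.22; camera adjusted p = 0.00393, and adjusted p = 0.902 with an estimated correlation). Cyt-c-p fell by 0.63 ± 0.10. ATPsynB, COX4 and UQCR-C2 fell, at log2 fold changes of -0.40 ± 0.088, -0.39 ± 0.089 and -0.38 ± 0.080, and lost the call with library totals alone. Of 35 genes of lipid storage and metabolism 14 fell and 1 rose, against 9 and 4 with library totals alone, and adjusted over the list alone 19 fell and 2 rose. Their median was -0.34 (camera adjusted p = 0.0188, and adjusted p = 0.776 with an estimated correlation), a call that ended with the block (0.0893) and without DHR39 replicate 3 (0.0662), in a range of 0.000663 to 0.0893. The lipoprotein gene apolpp fell by 0.71 ± 0.14, its receptor gene LpR1 fell by 0.66 ± 0.13 and Arc42 fell by 0.96 ± 0.16. Of 44 genes of glycolysis, trehalose and insulin signalling 10 fell and 2 rose, against 5 and 5 with library totals alone and 11 and 6 with the block, and adjusted over the list alone 18 fell and 4 rose (camera adjusted p = 0.115, but 0.00851 with voom, in a range of 0.00851 to 0.319). The glycogen phosphorylase gene GlyP fell by 0.90 ± 0.14, the trehalose synthesis gene Tps1 fell by 0.65 ± 0.13 and PyK fell by 0.53 ± 0.10.

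Hormone genes changed in part. Of 31 genes of ecdysteroid synthesis and response 4 rose and 6 fell, as also when adjusted over the list alone, against 6 and 4 with library totals alone and 5 and 5 with totals without the 50 most abundant genes, and 7 rose with the block (camera adjusted p = 0.672). The ecdysteroid synthesis enzymes sad and phm rose by 2.83 ± 0.34 and 2.42 ± 0.24 from low levels, 0.599 ± 0.287 and 0.926 ± 0.223 CPM in controls (edgeR adjusted p = 0.000119 and 2.6e-05). Npc2b rose by 0.61 ± 0.11 and Eip71CD fell by 0.64 ± 0.11. Of 19 nuclear receptors 3 fell and 0 rose, over all genes and adjusted over the list alone, against 2 and 2 with library totals alone and 3 and 2 with totals without the 50 most abundant genes, and 1 rose with the block (camera adjusted p = 0.954). This list shares 4 tested members with the ecdysteroid list. Those that fell were Hr39, Hr38, at -0.72 ± 0.16, and dsf, at -1.13 ± 0.31 (edgeR adjusted p = 0.0264). All 3 lie on arm 2L, and whether sequence linked to Hr39 accounts for the falls of Hr38 and dsf was not tested. The call of dsf ended without DHR39 replicate 1 (edgeR adjusted p = 0.0919), without DHR39 replicate 2 (0.110) and with the block (0.0642), in a range of 0.0120 to 0.110.

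Some genes were near absent in 1 genotype. CG31226 fell from 101 ± 24.2 to 0.0387 ± 0.0336 CPM, a ratio of 2810 with a 95% counting interval from 778 to 23205, and CG42876 fell from 12.1 ± 1.02 to 0.0576 ± 0.0997 CPM, a ratio of 224 with an interval from 76.6 to 1090 and all counts of DHR39 in replicate 1. The noncoding genes CR44534, CR45994, CR45346, CR44942, CR45353, CR44602, CR44050, CR44076 and CR44488 had no counts in DHR39, with bounds from at least 26.9-fold lower for CR44488 to at least 59.1-fold lower for CR44534 against 3 counts over the group. CG18557 rose by 5.99 ± 0.34, CG5070 by 4.18 ± 0.38 and CR43787 by 5.53 ± 0.57 (7.16 without control replicate 1 and 6.83 with the block), and lectin-24A rose with a ratio of 352 and an interval from 97.0. CR43787, CR45994 and CR44050 overlap other genes on their strand. SPH93 rose by 4.65 ± 0.93, and without DHR39 replicate 3 its log2 fold change was 2.44 (edgeR adjusted p = 0.0521, in a range of 1.8e-05 to 0.0671), against 5.77 without control replicate 2 and 5.40 with the block. Its call also ended with voom (adjusted p = 0.0671) and with a robust edgeR fit (0.0510). Intervals and bounds cover counting error only.

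**Figure D3:**
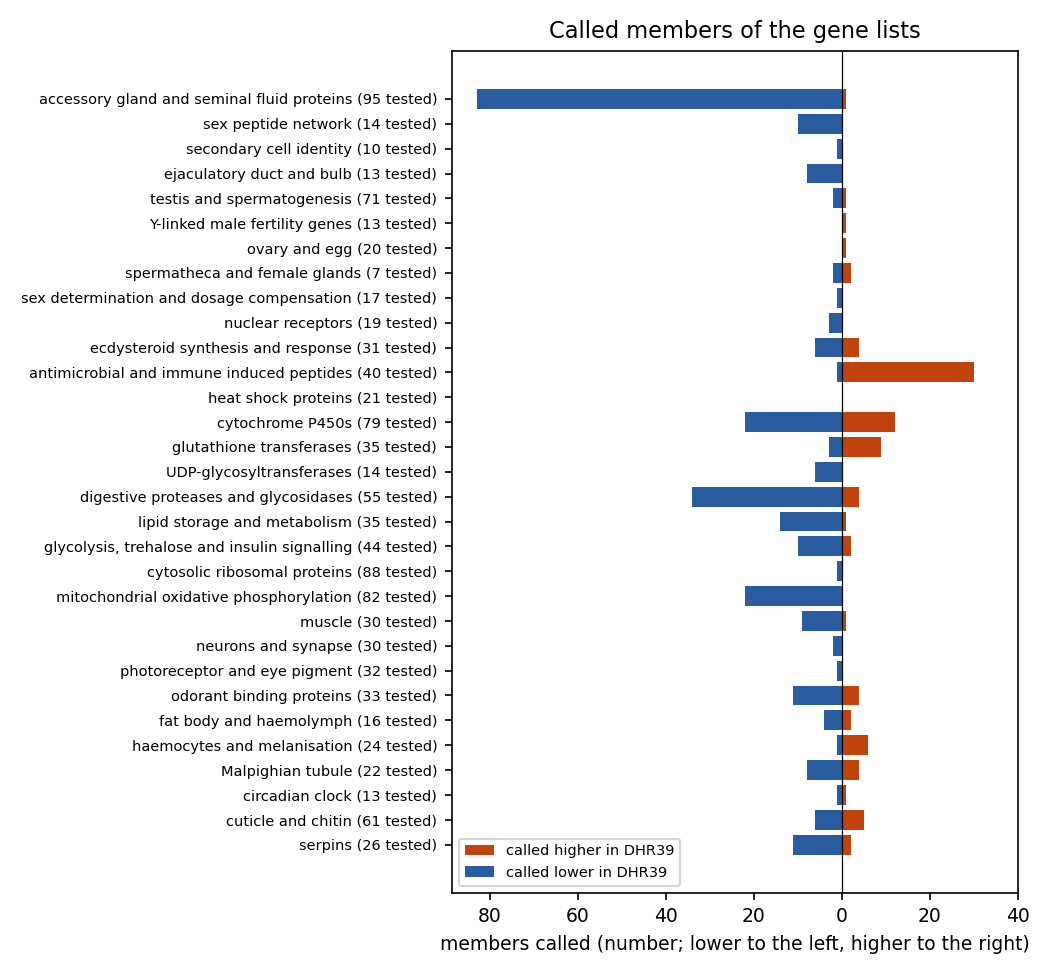
Number of members called by edgeR in each of 31 gene lists, lower in DHR39 to the left and higher to the right. The seminal fluid list reaches 83 lower and the antimicrobial list 30 higher.

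Each gene had an edgeR quasi-likelihood test with 6 residual degrees of freedom. Of 31 lists tested by camera with a preset correlation 12 were called, 4 higher and 8 lower. Of these the seminal fluid and duct lists, which share 4 tested members, were also called with an estimated correlation. By fry 13 lists were called, 9 of them among these 12. It did not call oxidative phosphorylation, haemocytes or glutathione transferases (fry adjusted p = 0.0536, 0.0643 and 0.127). Malpighian tubule, UDP-glycosyltransferases, muscle and glycolysis were called by fry (fry adjusted p = 0.00440, 0.0262, 0.0268 and 0.0488) but not by camera. Of all 56 ways to divide the 8 libraries into 5 and 3, 17, the real one included, gave as many called lists or more, so that number did not stand above other divisions. No other division called more than 1 gene. Every other division mixes the genotypes in at least 1 group, which widens the spread there, and some carry part of the genotype contrast. Neither count alone therefore decides on chance.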

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

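The tests of the antimicrobial rise, of near absence by chromosome arm, of genes near absent in DHR39 in the table for E7818.37 and of a common factor in the seminal fluid list were chosen only after the result was seen. Among 155 sets of 5 control values, 9 held 1 library far from the rest, and chance alone gives about 1 in 20. Control replicate 1 was high for CR43787, at 0.404 CPM. Control replicate 2 was high for Sfp60F, at 1185 CPM against 255 to 377 in the others, for l(2)k14505, at 23.8 CPM, and for the median of cytosolic ribosomal protein genes, at 0.12 on the log2 scale relative to the control mean. Control replicate 3 was high for Ugt86De, at 6.60 CPM, and Spn28B, at 51.9 CPM. Control replicate 4 was low for COX4, at 486 CPM, and grass, at 23.5 CPM, and high for per, at 58.4 CPM. Outside the comparison of the report, the authors' deposited table for the line E7818.37 holds 506 called genes, 239 higher and 267 lower, and gives Hr39 a log2 fold change of -0.015.

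Of the 56 divisions of the libraries, 1, the real one, reached 2333 genes changed, and the highest other gave 1. For genes changed at least 2-fold the real value was 929 and the highest other 1 (1 of 56). For seminal fluid genes called in 1 direction these were 83 and 0 (1 of 56). If all 56 are taken as equally likely, that share is under 0.05, and it is the smallest that 56 divisions can give. Every other division mixes the genotypes in at least 1 group, which widens the spread there. The real division parts all 3 pairs of the replicate names, as do 8 divisions in all, too few for a share under 0.05. With the pairs kept, chance division therefore cannot be excluded, and the others of these 8 gave 0 genes changed at most.

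The seminal fluid list was lower in DHR39. A scale set by a few abundant genes is argued against, since the list's median was -1.53 or lower under 4 other scalings. A smaller share of gland tissue alone would lower by 1 factor only those members that are made in the gland alone. The SD between 84 members, beyond their errors, was 0.87 on the log2 scale, and their log2 fold changes ran from -4.56 to 1.25. The rule set for this test was met, so the members did not fall by 1 common factor. The list shares 4 tested members with the duct and bulb list, and where each member is made was not tested, so this spread cannot decide. Less tissue may account for part or all of the fall, and an effect of the genotype on transcription stays open and untested. With 1 mutant line, other differences between the stocks cannot be told apart from an effect of Hr39. Without arm 2L, 50 of 57 tested members were called lower, at a median of -1.62. Sequence on that arm cannot account in cis for these 50, and may do so for members on 2L.

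The antimicrobial list was higher in DHR39. An infection of 1 library is argued against, since 22 or more of the 30 members called higher stayed called without each DHR39 library in turn. Haemocyte markers rose less than the list at the median, at 0.35 over 7 markers with an SD of 0.86, against 1.29. The rule set for this test, that median plus SD stay under the list's median, was met by a narrow margin. That SD is a spread between markers and not an error of their median, so more haemocytes cannot be excluded as part of the rise. Hml, the most abundant marker, was at 177 CPM in controls and 186 CPM in DHR39, while Sr-CI and NimC4 were called higher. A microbial load of the mutant cultures cannot be told apart from genotype with 1 mutant line, and in 3 of 3 pairs with the same replicate name the DHR39 library was higher.

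A set of 61 genes was near absent in 1 genotype, with a mean of at least 1 CPM in the other group and under 0.25 CPM in each library of the first. Sequence linked to Hr39 may account for part, since 31 of them lay on arm 2L (50.8%, against 19.3% of other tested genes), an odds ratio of 4.32 with a 95% interval from 2.52 to 7.39 by Fisher's exact test, and 14 of the other 30 on 2R, the other arm of that chromosome, an odds ratio of 2.64 with an interval from 1.19 to 5.77 among genes off 2L. It cannot account in cis for the 16 on 3L, 3R, X and Y, which leaves unlinked differences between stocks, or regulation, open. A state carried by the w1118 control stock cannot be told apart from one of the mutant in either direction, since the labels do not say whether E7818.37, the other line, shares that background. Of the 9 near absent in controls, the authors' deposited table for E7818.37 calls 0 higher by DESeq2 (0 at an unadjusted p under 0.05), at a median log2 fold change of 0.16, and of the 52 near absent in DHR39 it calls 7 lower (13.5%, against 1.88% of other tested genes) and 3 higher, at a median of -0.16, an excess of lower calls part of which may come from shared controls.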

How the results depend on the processing

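The replicate block was chosen after seeing the data, and the other alternatives were planned. The 83 seminal fluid genes called lower became 80 to 85 when 1 library was left out, 87 with the block, and 50 without arm 2L, where 57 were tested. Genes changed ran from 1566 without DHR39 replicate 3 to 3037 with library totals alone, and numbered 1373 at an adjusted p under 0.01 and 1364 against a 1.2-fold change, which are stricter by construction. With the block they numbered 2580, of which 2081 were shared. Hr39 was at -0.28 with library totals alone and between -0.51 and -0.36 without 1 library. S-Lap1, close to 0, changed sign, at 0.024 with upper quartile factors, 0.13 with library totals alone, 0.080 with totals without the 50 most abundant genes, and between -0.055 and 0.058 without 1 library. Under these scalings the median of all genes was at 0.036, 0.14 and 0.091, so both genes moved with a shift common to all genes; for libraries left out the cause was not tested. Lists called by camera went from 12 to 2 with an estimated correlation. Of 110 named called genes, 94 kept direction and call in each of 20 alternatives that gave an adjusted p; DESeq2 gave none for SPH93. The block changed no other call of a named gene or list than those given beside results. At this depth and number of libraries, 44.4% of simulated 1.5-fold changes were called, so smaller changes can be missed. That share need not hold in the data, where more genes were called than changed in the simulation.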

Other observations

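The counts of divisions per list below were chosen as tests only after the result for the number of lists was seen. Serpins, protease inhibitors several of which are seminal, fell in 11 of 26 tested genes and rose in 2 (4 with the block and 6 with library totals alone), and adjusted over the list alone 11 fell and 4 rose. Camera pointed down (adjusted p = 8.0e-06, and adjusted p = 0.209 with an estimated correlation), and the median log2 fold change of -0.091 turned to 0.052 with library totals alone. Spn28B, Spn38F and Spn75F fell, at -2.53 ± 0.17, -2.38 ± 0.15 and -1.99 ± 0.14, and 9 tested serpins are also in the seminal fluid list. Of 33 odorant binding proteins 11 fell and 4 rose, and adjusted over the list alone 14 fell and 5 rose (median -0.22; camera adjusted p = 0.0175, and adjusted p = 0.613 with an estimated correlation). That call ended without arm 2L (0.0573, in a range of 0.00354 to 0.0573). Obp51a, Obp56f and Obp56d fell, at -1.45 ± 0.12, -1.21 ± 0.13 and -1.14 ± 0.13, and 6 tested members are in the seminal fluid list. Of 22 Malpighian tubule genes 8 fell and 4 rose, against 4 and 5 with library totals alone, and adjusted over the list alone 11 fell and 5 rose (camera adjusted p = 0.148). The transporter gene Oatp58Db fell by 2.58 ± 0.16 and the urate oxidase gene Uro rose by 1.14 ± 0.16.

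Of 14 UDP-glycosyltransferases 6 fell and 0 rose, against 5 and 1 with library totals alone, and adjusted over the list alone 7 fell and 1 rose (camera adjusted p = 0.0641, but 0.0278 without DHR39 replicate 1, 0.0336 without control replicate 4, 0.0296 with library totals alone and 0.0271 with voom, among others, in a range of 0.0271 to 0.187). Ugt37b1 fell by 1.72 ± 0.31. Of 30 muscle genes 9 fell and 1 rose, against 5 and 3 with library totals alone, and adjusted over the list alone 10 fell and 2 rose (camera adjusted p = 0.116, but 0.0353 without DHR39 replicate 1 and 0.0142 with voom, in a range of 0.0142 to 0.202). The myosin heavy chain gene Mhc fell by 0.54 ± 0.092, the actin gene Act79B fell by 0.81 ± 0.12 and TpnC47D fell by 0.98 ± 0.14. Of 16 fat body and haemolymph genes 4 fell and 2 rose (4 with the block), and adjusted over the list alone 6 fell and 2 rose (camera adjusted p = 0.776). Of 61 cuticle and chitin genes 6 fell and 5 rose, against 5 and 7 with library totals alone, and adjusted over the list alone 6 fell and 5 rose (camera adjusted p = 0.871). Of 30 neuronal genes 2 fell (5 with the block), slo, at -0.34 ± 0.094, and nrv3, at -0.26 ± 0.078, and adjusted over the list alone edgeR called 0, with 6 lower at an unadjusted p under 0.05 and 4 by DESeq2 (camera adjusted p = 0.148, but 0.0268 without DHR39 replicate 2 and 0.00847 with voom, in a range of 0.00847 to 0.694). Both calls ended with library totals alone (edgeR adjusted p = 0.152 and 0.336), with totals without the 50 most abundant genes (0.0912 and 0.197) and without DHR39 replicate 3 (0.0928 and 0.154), in ranges of 0.00912 to 0.152 for slo and 0.00712 to 0.336 for nrv3. Further, slo lost its call without DHR39 replicate 1 (0.0940) and control replicate 4 (0.0536), and nrv3 without control replicate 4 (0.0851), control replicate 5 (0.0885) and DHR39 replicate 2 (0.121), and with upper quartile factors (0.0838).

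Of 32 photoreceptor and eye pigment genes 1 fell (2 with the block), st, at -0.65 ± 0.11, as also adjusted over the list alone, and 1 also rose with library totals alone (camera adjusted p = 0.599). Of 88 cytosolic ribosomal protein genes 1 fell, RpL5, at -0.25 ± 0.076 (edgeR adjusted p = 0.0429, and 0.124 with the block), a call that ended without each library in turn except control replicate 3, and with upper quartile factors (0.0855), library totals alone (0.360) and totals without the 50 most abundant genes (0.200), in a range of 0.00582 to 0.360. Adjusted over the list alone edgeR called 0, with 1 at an unadjusted p under 0.05 and 1 by DESeq2, while with library totals alone 0 fell and 2 rose (camera adjusted p = 0.871). Of 13 clock genes 1 rose and 1 fell (3 with the block), as also adjusted over the list alone, against 2 and 0 with library totals alone (camera adjusted p = 0.871). The gene per rose by 0.48 ± 0.13, a call that ended without DHR39 replicate 2 (edgeR adjusted p = 0.131) and control replicate 5 (0.0534), in a range of 0.00504 to 0.131. The gene to fell by 0.35 ± 0.10, a call that ended without control replicate 4 (edgeR adjusted p = 0.0591), DHR39 replicate 2 (0.0701) and DHR39 replicate 3 (0.135), and with upper quartile factors (0.0561), library totals alone (0.173) and totals without the 50 most abundant genes (0.111), in a range of 0.00510 to 0.173. Of 17 genes of sex determination and dosage compensation 1 fell (1 rose with the block and 3 with library totals alone), dsx, at -0.56 ± 0.13, as also adjusted over the list alone (camera adjusted p = 0.871). Of 20 ovary and egg genes 1 rose, yellow-g, by 1.15 ± 0.28, as also adjusted over the list alone (camera adjusted p = 0.954), a call that ended without DHR39 replicate 2 (edgeR adjusted p = 0.0751) and DHR39 replicate 3 (0.0626), in a range of 0.00581 to 0.0751. Of 7 genes of spermatheca and female glands 2 rose and 2 fell, against 3 and 1 with library totals alone, and adjusted over the list alone 3 fell and 3 rose (camera adjusted p = 0.741). Of 4 Turandot stress genes edgeR called 0, over all genes and adjusted over the list alone, with 1 at an unadjusted p under 0.05, 0 by DESeq2 and 1 with the block, and too few members were tested for camera.

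In the division of libraries, 17 of 56, the real one included, gave 12 or more lists called by camera with the preset correlation. The highest other gave 20, with 2 of the 3 DHR39 libraries in its group of 3. Divisions that place the DHR39 libraries unevenly carry part of the genotype contrast. The number of lists therefore cannot decide for or against chance, which is not excluded. Among the 8 divisions that part all 3 pairs, the highest other gave 19. Each list's median was therefore set against all 56 divisions. For 10 of 31 lists, among them 7 of the 12 called by camera (seminal fluid, sex peptide network, duct, antimicrobial, digestive, oxidative phosphorylation and lipid), the real median was larger in size than in every other division (two-sided exact permutation p = 0.0179, the smallest possible). Adjusted over the 31 lists this p was 0.0554, so 0 lists passed that adjustment, and 11 had an unadjusted p under 0.05. With this smallest p a list could pass only if more lists shared it, however large its own change. The adjustment therefore decides for no single list. For the other 5 lists called by camera, medians as large came from 49 of 56 divisions for glutathione transferases, 23 for serpins, 16 for haemocytes, 3 for odorant binding proteins and 3 for Y-linked genes, the real one included. A median need not move where only part of a list does. The mean log2 fold change was -0.72 for serpins and 0.28 for glutathione transferases, against medians of -0.091 and -0.027. Medians therefore cannot decide on the camera calls of these 2 lists.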
